A study of Homo sapiens with 60 samples.

How the data were processed

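The data are 60 libraries of human neuroblastoma lines in 27 groups: 32 of an 8-line panel, 16 of BE2c with a Luc or PRRX1 insert and 12 of SH-EP MYCNER clones. Per the labels' protocols, total RNA was treated with DNase I and libraries were prepared with a QuantSeq 3' mRNA kit for Illumina sequencing. The authors deposited whole-number counts of reads per gene for every library in one table of 57736 Ensembl identifiers. RSEM 1.2.3 and the build hg19 are listed in the submitters' processing notes, with no role or order; the aligner and the annotation are not given in the sources used here. The deposited counts were used as they stand, with no coordinates. Names were taken from a table of gene names for 39501 identifiers and from GENCODE v29 for 12784, and 5451 stayed without a name. Mitochondrially encoded genes were not analysed here.

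Panel totals had a median of 5.26 M counts, BE2c 4.3 M and clones 25.51 M; the top 10 genes took 3.64% to 7.96% of a library. Replicate pairs differed by more than counting noise (chi-square per degree of freedom 3.073 to 27.119 over genes with at least 20 counts in the pair), and their log2 CPM correlated at 0.9665 to 0.9953, so no library was taken as a copy of another.

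Groups were read from the sample titles. The panel lines were assigned to a mesenchymal (SH-EP, SK-N-AS, GI-M-EN, CHP-212) or adrenergic (Kelly, NLF, SK-N-DZ, IMR5) state from general knowledge of these lines, since the labels do not give it. Comparisons, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Exceptions are tests in the closing section, named there as chosen after the result was seen or as addressing patterns already seen. Libraries were scaled by TMM, genes filtered with filterByExpr on the groups, and comparisons tested with edgeR 4.0.16 quasi-likelihood F tests in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every edgeR adjusted p in the text is of this kind. All panel libraries were fitted together with 16 residual degrees of freedom, BE2c libraries with 8. For mesenchymal against adrenergic lines the counts of the libraries of one line and treatment were summed and the line was the replicate, with 6 residual degrees of freedom; for guide pairs the libraries of a clone were summed and the clone was the replicate, with 3. Genes tested numbered 16729 in the panel, 13618 for water levels between states, 15402 for the difference in response, 13834 in BE2c and 17180 in clones. Standard errors are the absolute log2 fold change over the square root of F. CPM values use the TMM-scaled library sizes of the same fits, and ranges over single libraries use total counts.

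Named genes were, per comparison, a fixed set of checks (among them TLR3, MYD88, PRRX1, MYCN, IFIT1, ISG15, CXCL10, IL6, IFNB1 and HAND2), the 6 higher and 6 lower genes with the largest change that passed the test, with a mean log2 CPM of at least 2 and libraries that did not overlap, and up to 4 members of each list with the smallest adjusted p; the text gives a selection of them, and some named genes are not reported here. That libraries did not overlap was required only where 2 groups were compared, not in tests of a difference of effects. CCL5, also among the fixed checks, was not analysed here. Where a group had 0 counts in all its libraries the fold is a bound against a floor of 3 counts over all libraries of that group together, and with 1 to 3 counts it is a ratio with an exact interval. Such bounds and intervals cover counting error only. Genes with close copies (HLA, IFIT, OAS, keratin and interferon families) and overlapping genes are uncertain, because how reads were shared between them is not given in the sources used here.

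The 17 lists, with 498 entries of which 492 had an identifier, covered interferon-stimulated genes, cytokines, NF-kappaB targets, class I antigen presentation, sensing of double-stranded RNA, mesenchymal and adrenergic markers, matrix, MYC and ribosome genes, cell cycle, cell death, integrated and endoplasmic reticulum stress, cholesterol synthesis, hypoxia and glycolysis, nuclear oxidative phosphorylation, Schwann cell and precursor markers, and markers of leukocytes, endothelium and epithelium. They were written from general knowledge. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 17 lists per comparison. They were tested again with the correlation estimated. Medians are over the measured members. Medians with 0-count genes at their bound also leave out members with at most 3 counts over the libraries of each group. List scores per line are means of log2 fold changes and were tested over all 70 assignments of the lines.

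Alternatives were the DESeq2 1.42.0 Wald test, RLE size factors, no low-count filter, fits of only the libraries compared, a block for the replicate number, single libraries as replicates, and leaving out each library, line or clone. The tests were checked on simulated counts with known changes; for 4-fold changes they found 74.2% in the IMR5 comparison, 15.2% for water levels between states, 75.8% for the difference in response, 86.4% for BE2c Luc DMSO and 63.6% for TLR3/Rosa against control clones. In the simulated water comparison 1.49% of 2-fold changes were found, in the simulated difference in response 23.9%. Each simulated gene took the spread of the trend at its level, without the variation around it that real genes have. All these shares may therefore be too high. The mean responses of each state group on their own, genes without a name and comparisons between the 3 sets of libraries were not used here. XIST and Y-linked genes were left out of the named genes.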

Results

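RNA-seq counts were examined for 60 libraries of human neuroblastoma cell lines, made with QuantSeq, a method that reads only the 3' end of polyadenylated transcripts. A panel of 8 lines received poly(I:C), a synthetic double-stranded RNA that stands in for viral RNA, at 30 µg/mL for 24 hours, or water, with 2 libraries per line and treatment. The line BE2c carried an insert of luciferase (Luc) or of PRRX1, a homeobox transcription factor of mesenchymal cells, and was given doxycycline at 1 µg/mL for 14 days or the solvent DMSO, then poly(I:C) or water, with 2 libraries in each of 8 groups. Clones of SH-EP MYCNER, whose name points to a fusion of MYCN with the estrogen receptor, carried guide RNA pairs against luciferase and Rosa26, TLR3 and Rosa26, or TLR3 and MYD88, with 2 clones per pair and 2 libraries per clone. Totals ran from 3.44 to 7.44 M counts in the panel, 3.55 to 5.39 M in BE2c and 23.51 to 27.06 M in the clones. Nothing in the labels says that replicates were separate cultures, so the p-values below may measure technical spread only.

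The first question was whether TLR3, the endosomal receptor of double-stranded RNA, was present in each line. TLR3 was counted in all 8 water libraries of SH-EP, SK-N-AS, GI-M-EN and CHP-212, the lines assigned here to the mesenchymal state from general knowledge rather than from the labels, at 0.405 to 7.68 CPM (counts per 1 M counts). It was at 0 in 7 of the 8 water libraries of Kelly, NLF, SK-N-DZ and IMR5, assigned to the adrenergic state, and at 1 count in the other. After poly(I:C) it stood at 55 to 341 counts in the mesenchymal libraries and at 0 in all 8 adrenergic ones.

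**Figure D1:**
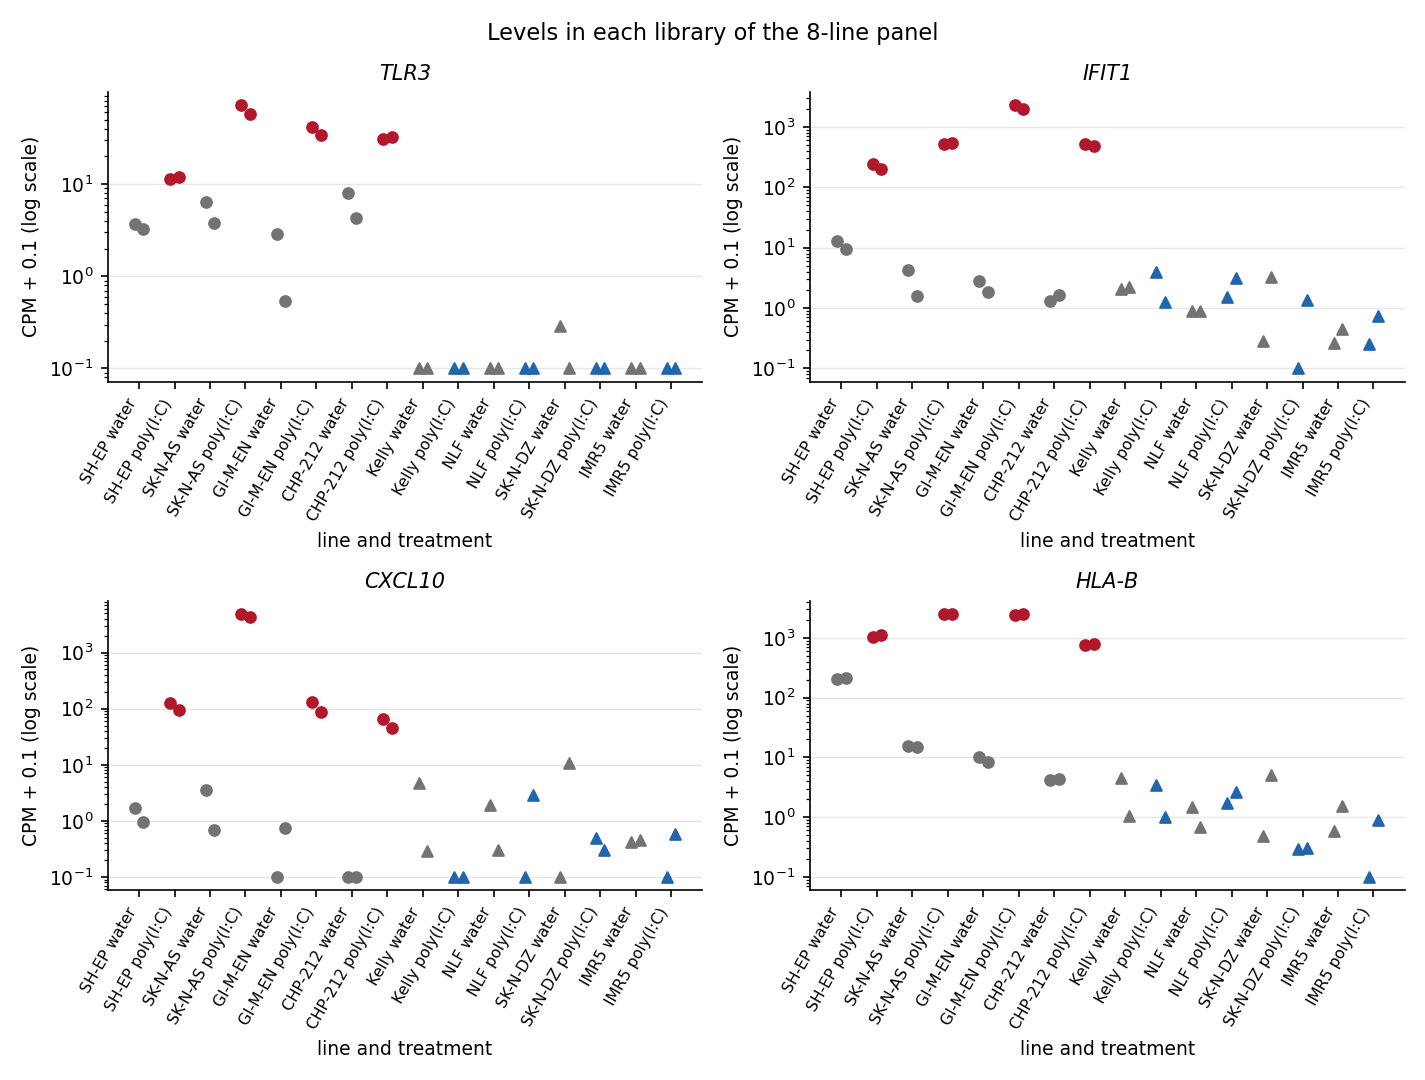
Level of TLR3, IFIT1, CXCL10 and HLA-B in each of the 32 panel libraries, 2 per line and treatment, as CPM + 0.1 on a log scale; circles are mesenchymal lines, triangles adrenergic lines, grey points water and coloured points poly(I:C). After poly(I:C), TLR3 averaged 11.6 CPM in SH-EP, 64.5 in SK-N-AS, 37.8 in GI-M-EN and 31.7 in CHP-212, against 0 in the adrenergic lines.

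What poly(I:C) changed was asked line by line, starting with SH-EP, a substrate-adherent mesenchymal line without MYCN amplification. TLR3 rose from 3.38 ± 0.328 to 11.6 ± 0.264 CPM (mean ± SD, n = 2 against 2), a log2 fold change of 1.77 ± 0.40 (± standard error, as for all fold changes below; edgeR adjusted p = 0.00389). Interferon-stimulated genes rose nearly as a whole: 41 of 44 measured were higher and none lower, with a median of 3.05 (camera adjusted p = 5.22e-81). The median was 3.08 with genes at 0 counts set to their bound. Such medians, here and below, also leave out members with at most 3 counts in each group. IFIT1, which binds foreign RNA, rose by 4.32 ± 0.24, ISG15, a ubiquitin-like modifier, by 6.39 ± 0.31, IFI27 by 8.39 ± 0.38, IFI44L by 8.28 ± 0.36 and OAS2, a double-stranded RNA sensor, by 7.95 ± 0.26. Of 27 cytokine genes 22 rose, among them CXCL10, an attractant of T cells, by 6.46 ± 0.61, IL6 by 4.94 ± 0.43, CXCL11 by 6.43 ± 0.44 and IL11 by 2.70 ± 0.16. NF-kappaB targets rose less, 18 of 27 with a median of 0.99, led by SOD2 at 1.86 ± 0.14 and TNIP1 at 1.77 ± 0.14. Class I antigen presentation genes rose in 17 of 20, with B2M at 1.51 ± 0.09 and HLA-B at 2.36 ± 0.20, and sensors in 11 of 24, with IFIH1 at 3.04 ± 0.18 and RIGI at 3.30 ± 0.20.

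Cell death genes also rose in SH-EP, in 16 of 24 with a median of 0.71, and the largest mover was XAF1 at 5.78 ± 0.25, itself induced by interferon. Stress genes rose in 10 of 22 and fell in 2, with DDIT3, a transcription factor of the unfolded protein response, at 1.90 ± 0.24 and SESN2, a stress-induced sestrin, at 0.60 ± 0.13 (camera adjusted p = 0.00453, and adjusted p = 0.0601 with an estimated correlation). Mesenchymal markers rose in 7 and fell in 2 of 41 (camera adjusted p = 0.0828), adrenergic markers moved in 3 each way of 42 (adjusted p = 1), and cell cycle genes fell in 5 and rose in 1 of 35 (adjusted p = 0.0595). BFSP1 at −2.34 ± 0.43 and GYG2, a primer of glycogen synthesis, at −2.33 ± 0.39 had among the largest decreases of a named gene. In all, 1127 genes were higher and 1077 lower of 16729 tested at an edgeR adjusted p below 0.05. The 2204 calls came to 1270 without water replicate 1, 1313 without poly(I:C) replicate 1 and 1443 without poly(I:C) replicate 2.

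SK-N-AS, a mesenchymal line without MYCN amplification, changed the most genes, 3400 higher and 3425 lower. TLR3 rose from 5.01 ± 1.84 to 64.5 ± 10.2 CPM, by 3.69 ± 0.36 (edgeR adjusted p = 1.5e-08). Every one of the 27 measured cytokine genes rose, with a median of 8.24, or 7.22 with genes at 0 counts set to their bound. CXCL10 went from 2.00 ± 1.99 to 4660 ± 403 CPM and IL11 rose by 6.81 ± 0.19. The interferon gene IFNL1, at 0 in both water libraries, reached 377 ± 58.7 CPM, at least 1620-fold more. Interferon-stimulated genes rose in 43 of 44 with a median of 4.96, NF-kappaB targets in 27 of 27 with a median of 4.41 and class I genes in 20 of 20 with a median of 3.13. Examples were BIRC3, an NF-kappaB-induced inhibitor of cell death, at 8.46 ± 0.25 and HLA-B at 7.35 ± 0.26.

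In SK-N-AS all 35 cell cycle genes fell, with a median of −1.65 (camera adjusted p = 1.39e-23, and 0.000134 with an estimated correlation), including BIRC5, which acts in chromosome segregation, at −2.08 ± 0.11 and the nucleotide synthesis genes RRM2 at −2.22 ± 0.12 and TYMS at −2.54 ± 0.15. Among the lower genes were the proneural factor NEUROG2 at −5.39 ± 0.31 and INSM1, a zinc finger factor of neuroendocrine cells, at −4.67 ± 0.48. Of 42 adrenergic markers 23 fell and 5 rose, with a median of −0.92, or −1.11 with 0-count genes at their bound (camera adjusted p = 1.08e-05, and adjusted p = 0.0739 with an estimated correlation); GATA3 stood at −1.45 ± 0.09. Mesenchymal markers rose in 30 and fell in 1 of 41, with a median of 1.30 (camera adjusted p = 3.81e-11), among them the hyaluronan receptor CD44 at 3.64 ± 0.14 and JUN at 2.89 ± 0.14. Matrix genes rose in 23 and fell in 2 of 35, with the basement membrane collagens COL4A1 at 5.45 ± 0.20 and COL4A2 at 4.77 ± 0.22. Hypoxia and glycolysis genes rose in 16 and fell in 1 of 21, with VEGFA at 3.34 ± 0.20. Cholesterol synthesis genes fell in 14 and rose in 2 of 21 (camera adjusted p = 6.48e-05), with FDPS at −1.59 ± 0.11. Nuclear genes of oxidative phosphorylation fell in 22 of 35 and rose in none, by a median of −0.43 (camera adjusted p = 8.04e-07, and 0.0402 with an estimated correlation). MYC and ribosome genes fell in 18 and rose in 1 of 31 by a median of −0.43. Stress genes rose in 16 and fell in 3 of 22, with XBP1 at 2.78 ± 0.14 and GDF15 at 3.92 ± 0.24.

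In GI-M-EN, another mesenchymal line, all 44 interferon-stimulated genes rose, by a median of 6.57, with IFIT1 going from 2.26 ± 0.695 to 2142 ± 209 CPM and ISG15 rising by 8.35 ± 0.33. TLR3 rose by 4.50 ± 0.44 (edgeR adjusted p = 1.6e-08), and MYD88, the adaptor of most other Toll-like receptors, from 16.7 ± 6.12 to 173 ± 18.6 CPM. IFNB1, at 0 in water, reached 28.6 ± 14.8 CPM, at least 90.7-fold more, though it did not pass by DESeq2 (adjusted p = 0.427). ICAM1, an adhesion molecule for leukocytes, rose 3060-fold with a counting interval of 1050 to 14800, and CD74, the invariant chain of class II antigen presentation, rose at least 383-fold from 0. NF-kappaB targets rose in 26 of 27 with a median of 4.14, class I genes in 19 of 20 with a median of 4.53 and sensors in 17 of 24 with a median of 2.19. SOD2 rose by 6.36 ± 0.18 and IFIH1 by 7.15 ± 0.19. Of 27 cytokine genes 17 rose and 1 fell, with IL32, a cytokine induced in inflamed tissue, at 8.88 ± 0.32.

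State markers in GI-M-EN split. Mesenchymal markers rose in 14 and fell in 13 of 41 (camera adjusted p = 0.181), with ID3 at 2.91 ± 0.17 and CD44 at 2.07 ± 0.12, and adrenergic markers fell in 11 and rose in 5 of 42 (adjusted p = 0.0709), with HAND2 at −1.54 ± 0.09 and GATA3 at 2.16 ± 0.09. The keratins KRT19 and KRT18, markers of epithelia, were lower at −4.14 ± 0.44 and −3.13 ± 0.16, and CD68, a lysosomal protein of macrophages, rose by 6.50 ± 0.31. That list of other cell types had a median of −2.45 over 6 genes, or −1.77 with 0-count genes at their bound (camera adjusted p = 0.0324, and adjusted p = 0.0572 with an estimated correlation), but 0 without the low-count filter (adjusted p = 0.429), and it did not pass without poly(I:C) replicate 1 (adjusted p = 0.0578). Cell cycle genes fell in 18 of 35 and rose in none, by a median of −0.39 (adjusted p = 1.61e-05, and adjusted p = 0.0572 with an estimated correlation). Cholesterol synthesis genes rose here, 11 higher and 2 lower of 21, with HMGCS1 at 1.38 ± 0.13. The test called 3000 genes higher and 3096 lower.

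CHP-212, a mesenchymal-leaning line with high MYCN, had 1235 genes higher and 810 lower. Interferon-stimulated genes rose in 43 of 44 with a median of 5.93; IFIT1 rose by 8.50 ± 0.33 and OAS2, at 0 in water, by at least 2410-fold. TLR3 rose from 6.11 ± 2.68 to 31.7 ± 1.37 CPM (edgeR adjusted p = 4.2e-05). All 20 class I genes rose, with HLA-B at 7.55 ± 0.29 and B2M at 2.04 ± 0.09. Cytokine genes rose in 12 of 27, with IL32 at 8.15 ± 0.39 and CXCL10 at least 207-fold from 0. The median over this list was 2.19. It was 4.40 with 0-count genes at their bound and members with at most 3 counts in each group left out. NF-kappaB targets rose in 16 of 27, by a median of 0.81. Mesenchymal markers rose in 18 of 41 and fell in none (camera adjusted p = 1.41e-10), with IFI16, a DNA sensor, at 2.76 ± 0.17 and ITGA5, the fibronectin-binding integrin chain, at 1.56 ± 0.18, and matrix genes rose in 19 of 35. The list of leukocyte, endothelial and epithelial markers had 3 higher and 1 lower of 6 (camera adjusted p = 0.0434, and adjusted p = 0.0649 with an estimated correlation), and did not pass with a replicate block, without the low-count filter or without water replicate 1 (adjusted p = 0.0601, 0.453 and 0.081). MYCN was at 2161 ± 17.7 CPM in water and 1306 ± 71.7 after poly(I:C), a difference that did not pass (adjusted p = 0.0901). Lower were ACO1, which switches between aconitase and iron sensor, at −3.51 ± 0.19 and CHODL at −3.24 ± 0.16. The 2045 calls came to 1353 without water replicate 1, 1282 without water replicate 2 and 1233 without poly(I:C) replicate 1.

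**Figure D2:**
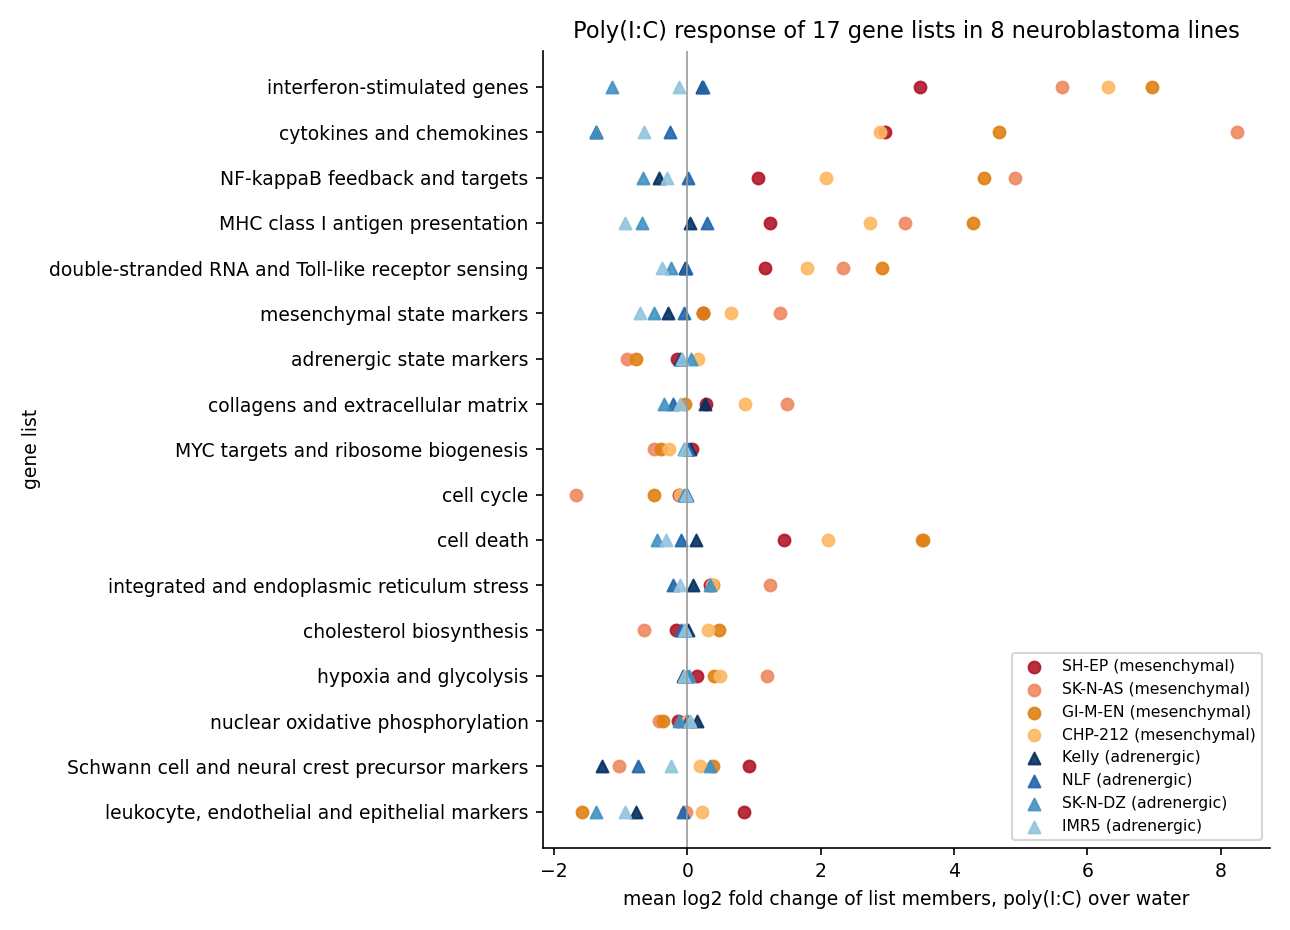
Mean log2 fold change of each of 17 gene lists in each of 8 lines (2 poly(I:C) against 2 water libraries per line); circles are mesenchymal and triangles adrenergic lines. The interferon list averaged 5.59 over the 4 mesenchymal lines and −0.2 over the 4 adrenergic lines.

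The same treatment was then examined in the 4 adrenergic lines, all of them with abundant MYCN transcript: in water, Kelly had 3163 ± 103 CPM, NLF 341 ± 20.6, SK-N-DZ 1132 ± 34.8 and IMR5 1101 ± 213 (n = 2 each). No interferon-stimulated gene passed the test in any of the 4. IFIT1 stood at a log2 fold change of 0.29 ± 0.64 in Kelly, 1.46 ± 0.81 in NLF and −1.27 ± 0.96 in SK-N-DZ, each with an edgeR adjusted p of 1. Kelly had 3 genes higher, including MYL6, a myosin light chain, at 0.45 ± 0.08, from 240 ± 5.03 to 328 ± 3.70 CPM. NLF had 2 lower, including CHAC1, a glutathione-degrading enzyme, from 16.7 ± 0.601 to 6.07 ± 0.117 CPM. IMR5 had 0 genes by edgeR, with 606 below an unadjusted p of 0.05, 1 gene by DESeq2, 62 without the low-count filter and 15 with the line fitted alone. The count in Kelly was 14 without water replicate 1, 0 without water replicate 2 or poly(I:C) replicate 1, 31 by DESeq2, 57 with a replicate block, 117 without the filter and 113 with the line fitted alone, and that in NLF was 1 without either water replicate or poly(I:C) replicate 1, 51 without the filter and 6 with the line fitted alone. MYL6 and CHAC1 did not pass without any 1 of the 4 libraries of their line, nor CHAC1 with the line fitted alone (adjusted p = 0.0788). In a simulation of the IMR5 comparison the test found 32.8% of genes changed 1.5-fold, 55.2% of those changed 2-fold and 74.2% of those changed 4-fold. Simulated genes, here and in the simulations below, took the spread of the trend without variation around it, so the shares may be too high. They were set at their mean level over all panel libraries. These shares therefore do not hold for genes near 0 counts in the adrenergic lines, such as TLR3.

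SK-N-DZ had 3 genes higher and 8 lower. The inhibitors of differentiation ID1, ID2 and ID3, which are targets of BMP signalling, fell, at −1.78 ± 0.19, −1.35 ± 0.15 and −1.44 ± 0.18, and SESN2 rose by 0.66 ± 0.12. With the 4 libraries of the line fitted alone ID1, ID3 and SESN2 did not pass (adjusted p = 0.0815, 0.22 and 0.499), though the fold changes held at −1.78, −1.44 and 0.65. The stress list was higher in SK-N-DZ with a median of 0.39 over 22 genes (camera adjusted p = 7.02e-11, and 0.000887 with an estimated correlation), 1 of them passing over all genes and 7 when adjusted over the list alone. Interferon-stimulated genes had a median of −0.86 there (adjusted p = 6.85e-07, and adjusted p = 0.303 with an estimated correlation), with 2 lower when adjusted over the list alone, but the median was 0.04 without water replicate 2 (adjusted p = 0.794). The count of 11 in this line is loose: it was 132 without poly(I:C) replicate 2, 25 without water replicate 1, 7 without water replicate 2, 28 by DESeq2, 30 with a replicate block, 93 without the low-count filter and 2 with the line fitted alone.

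Whether the state groups differed before treatment was tested with the line as the replicate, 4 against 4. Higher in mesenchymal lines were S100A6, a calcium-binding protein, at 1762 ± 1395 against 4.56 ± 3.38 CPM, LTBP2, a matrix protein, by 8.39 ± 1.22, FUCA2, a fucosidase, by 7.78 ± 0.78, the membrane protease MMP14 by 7.09 ± 1.03 and NT5E, an ectoenzyme that makes adenosine, by 6.57 ± 0.85. Lower were the neural factors POU3F2 at −4.92 ± 0.59 and ONECUT2 at −3.55 ± 0.49, and ST8SIA2, which makes polysialic acid, at −6.86 ± 0.97. Among sensors, IFIH1 stood at 11.9 ± 3.13 against 0.433 ± 0.183 CPM (edgeR adjusted p = 0.0219), and TLR3 at 4.17 ± 2.01 against 0.0273 ± 0.0546 CPM, a ratio of 172 with a counting interval of 30.5 to 6820 (adjusted p = 0.0461). Neither call was firm: TLR3 had an adjusted p of 0.0611 to 0.229 on leaving out any 1 line but NLF and 0.0879 without the low-count filter, and IFIH1 one of 0.0602 to 0.097 without SH-EP, GI-M-EN, Kelly, SK-N-DZ or IMR5. MYD88 at 2.41 ± 0.65, MYCN at −1.40 ± 1.88 and PRRX1 at −0.30 ± 1.88 did not pass.

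Of the lists in water, mesenchymal markers had a median of 2.97 over 38 genes, with 2 passing over all genes and 15 when adjusted over the list alone (camera adjusted p = 8.79e-12, and adjusted p = 0.121 with an estimated correlation). Adrenergic markers had a median of −1.84 over 37, none passing (adjusted p = 2.63e-09, and adjusted p = 0.169 with an estimated correlation). The markers did not all follow the assigned state in every line: the adrenergic list had a mean log2 CPM of 5.08 in SK-N-AS, above NLF at 4.21 and IMR5 at 4.88, and PRRX1 was at 130 ± 9.58 CPM in IMR5 and 0.57 ± 0.0519 CPM in GI-M-EN. The mesenchymal list did separate the lines, with a mean log2 CPM of 4.51 to 6.38 in mesenchymal and 2.01 to 4 in adrenergic lines. These marker lists come from general knowledge of the same states and are no independent evidence of direction. Class I genes had a median of 2.48 over 18, with 14 higher when adjusted over the list alone (adjusted p = 7.34e-11, and adjusted p = 0.121 with an estimated correlation). The test called 26 genes higher and 8 lower of 13618. Of the 35 ways to split 8 lines into 4 and 4 only the real one reached 34 calls, the next highest having 2, but the count was 0 without GI-M-EN, Kelly or SK-N-DZ, 3 without IMR5, 4 without SH-EP, 15 without CHP-212, 53 without SK-N-AS and 188 without NLF. DESeq2 called 960, and with each library as a replicate the count was 9736.

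The difference in response between the state groups was tested directly. ISG15 differed by 6.95 ± 0.48 (edgeR adjusted p = 0.00059), IFI27 by 10.29 ± 0.49 (adjusted p = 3.57e-05), IFIT1 by 7.21 ± 1.40 and IFI44L by 7.88 ± 0.59. In all, 30 of 43 interferon-stimulated genes rose more in mesenchymal lines, 42 when adjusted over the list alone, and the median difference was 5.35 (camera adjusted p = 2.21e-38, and adjusted p = 0.287 with an estimated correlation). Differences also passed for B2M at 3.04 ± 0.59, the proteasome activators PSME1 at 1.36 ± 0.23 and PSME2 at 1.72 ± 0.24, the sensors RIGI at 5.48 ± 0.73 and EIF2AK2 at 2.18 ± 0.27, the growth factor CSF1 at 3.16 ± 0.62 and the stress genes DDIT3 at 1.80 ± 0.35 and HSPA5 at 0.90 ± 0.18. Lower in the mesenchymal response were NEUROG2 at −5.54 ± 0.87, the neurite factor DPYSL5 at −3.13 ± 0.48 and the RNA-binding proteins CELF3 at −3.13 ± 0.59 and ELAVL3 at −2.57 ± 0.37, which without SK-N-AS stood at −1.68, −1.26, −1.55 and −1.66 and did not pass. None of the 4 passed without any 1 adrenergic line (adjusted p = 0.057 to 0.179). NEUROG2 did not pass by DESeq2 either (adjusted p = 0.683), and with each library as a replicate NEUROG2 at −2.08 and CELF3 at −1.80 did not pass. TLR3, with almost no counts in the adrenergic lines, did not pass as a difference (adjusted p = 0.479). The test called 132 genes higher and 115 lower; of 35 splits only the real one reached 247, the next highest having 3. The count was 49 without Kelly, 56 without NLF, 51 without SK-N-DZ or IMR5, 687 without SH-EP and 602 without CHP-212, while DESeq2 called 1231, and it was 633 without the low-count filter and 4705 with each library as a replicate. IFIT1, B2M, DDIT3 and HSPA5 did not pass without SK-N-AS or without any 1 adrenergic line.

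List scores per line gave the coarsest test, an exact one over the 70 assignments of 8 lines, in which no p can be below 0.0286. That smallest value was reached by 9 lists, among them interferon-stimulated genes with a difference of 5.79, cytokines with 5.60, NF-kappaB targets with 3.47, class I genes with 3.20, cell death with 2.84 and cell cycle with −0.57. Adjusted over 17 lists, the exact permutation test gave each of them p = 0.054. With list medians in place of means the interferon list differed by 5.28 (exact test, adjusted p = 0.0695), and with only members at 1 CPM or more in every line by 4.89 over 13 genes (adjusted p = 0.0445, over the 14 lists with such members).

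BE2c, a MYCN-amplified line from a bone marrow metastasis, served to ask what PRRX1 does in such a line. In water, doxycycline raised PRRX1 from 5.67 ± 3.12 to 237 ± 169 CPM in the PRRX1 cells (edgeR adjusted p = 5.36e-07), and with the Luc insert PRRX1 stayed at a ratio of 2.37 with a counting interval of 0.541 to 14.2. Genes that rose in the PRRX1 cells included CCN2, a matrix-associated growth factor, from 0.716 ± 0.294 to 281 ± 55.4 CPM, fibronectin (FN1) from 44.5 ± 1.80 to 1294 ± 286 CPM, TAGLN, an actin-binding protein of smooth muscle, by 6.63 ± 0.26 against 2.45 ± 0.50 with Luc, CAVIN1, a coat protein of caveolae, by 5.96 ± 0.35, and the receptor kinase AXL by 3.68 ± 0.33. Matrix genes rose in 21 and fell in 3 of 30, with a median of 1.66 (camera adjusted p = 2.65e-13, and 0.00782 with an estimated correlation), SPARC at 3.58 ± 0.17 and TIMP3 at 4.16 ± 0.16 among them and DCN, decorin, lower at −4.09 ± 0.16. Mesenchymal markers rose in 20 and fell in 3 of 34, with a median of 1.03 (adjusted p = 1.32e-07, and 0.00452 with an estimated correlation).

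Adrenergic markers fell in 21 and rose in 7 of 42, with a median of −0.53 (camera adjusted p = 2.89e-06, and 0.00452 with an estimated correlation). Among them were DBH, which makes noradrenaline, at −2.17 ± 0.15, the noradrenaline transporter SLC6A2 at −1.74 ± 0.11 and the granule protein CHGA at −1.74 ± 0.13. MYCN fell from 3617 ± 187 to 1431 ± 147 CPM (edgeR adjusted p = 4.14e-06), and MYC and ribosome genes fell in 9 and rose in 2 of 30. Stress genes fell in 18 and rose in 2 of 23, with a median of −2.13 (adjusted p = 1.66e-14, and 0.0314 with an estimated correlation): TRIB3, a pseudokinase induced by ATF4, at −4.04 ± 0.17, CHAC1 at −3.98 ± 0.25 and SESN2 at −3.37 ± 0.20, with the cystine transporter SLC7A11 outside the list at −5.64 ± 0.27. Class I genes rose in 11 and fell in 3 of 19, with HLA-B at 4.38 ± 0.56 (camera adjusted p = 0.000204, and 0.0434 with an estimated correlation), and interferon-stimulated genes in 16 against 2 of 43, with IFIT1 at 3.36 ± 0.82 (adjusted p = 0.000106 for the list, and adjusted p = 0.26 with an estimated correlation). IFIT1 did not pass by DESeq2 (adjusted p = 0.112) or without DMSO replicate 1 (adjusted p = 0.0502). Cholesterol synthesis genes rose in 12 and fell in 1 of 21 (adjusted p = 0.000116, and adjusted p = 0.0685 with an estimated correlation). TLR3 was at 0.716 ± 0.225 CPM with doxycycline and 0 without (adjusted p = 0.0595). The test called 1905 genes higher and 1874 lower, and the 3779 calls came to 2460 without DMSO replicate 1 and 2334 without DMSO replicate 2.

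**Figure D3:**
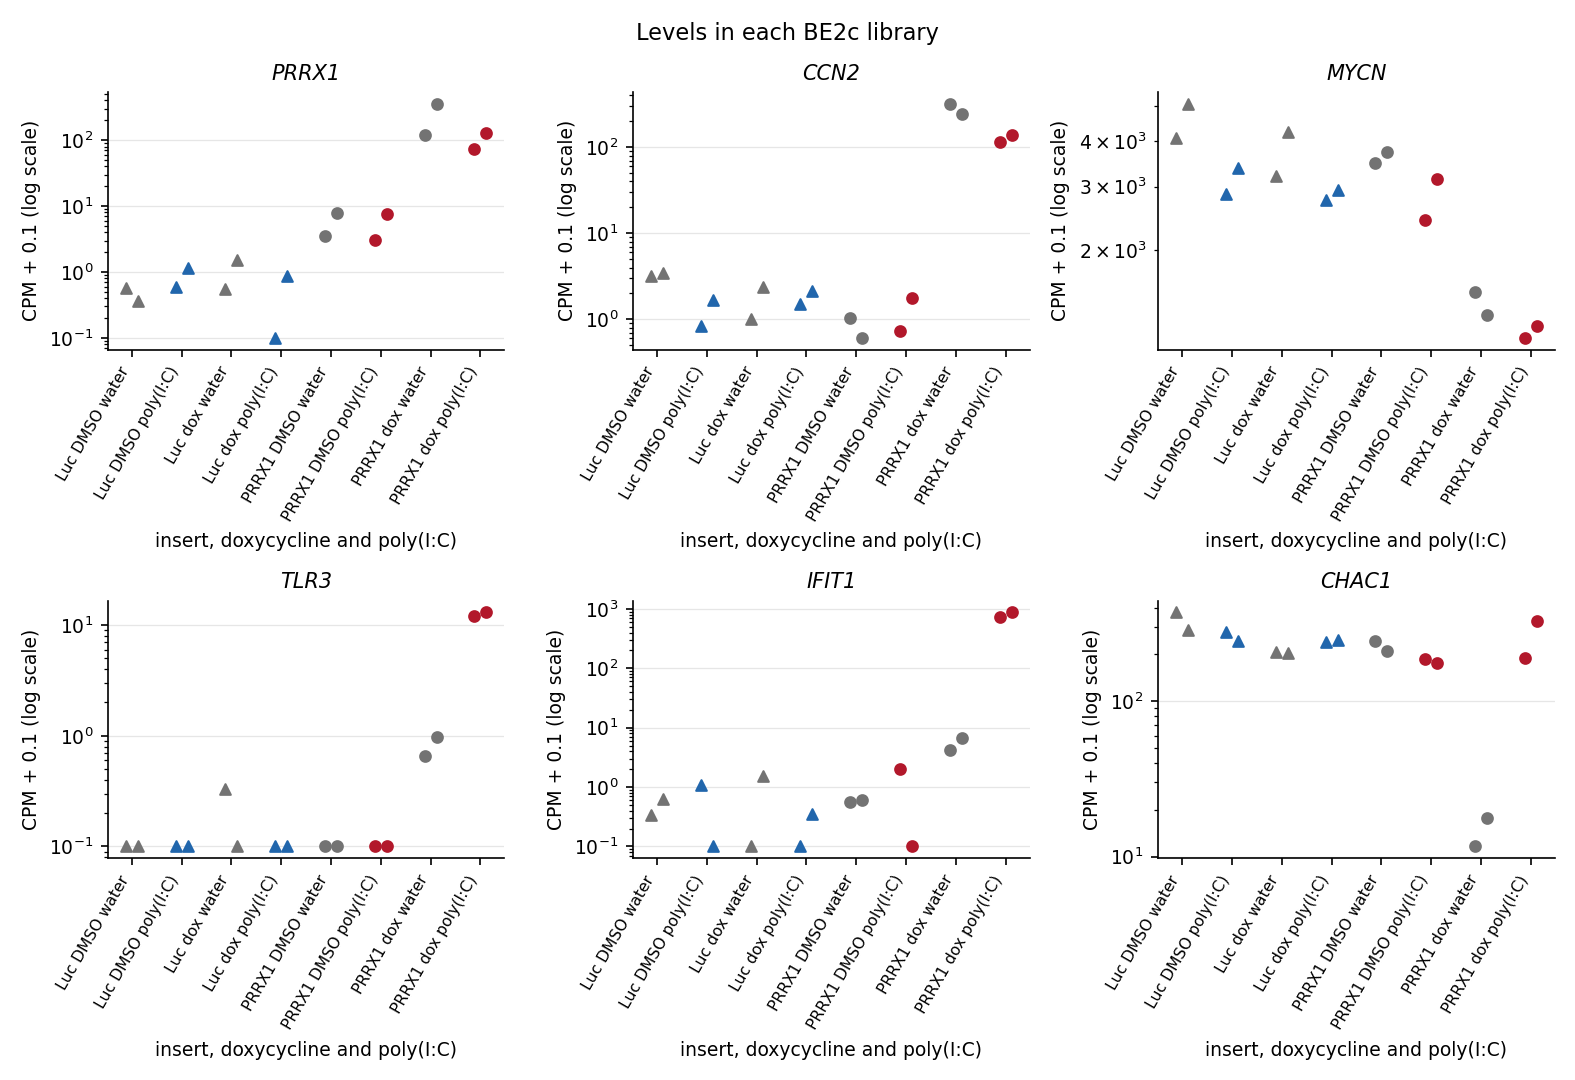
Level of 6 genes in each of 16 BE2c libraries, 2 per group, as CPM + 0.1 on a log scale; circles carry the PRRX1 insert and triangles Luc, grey points water and coloured points poly(I:C). TLR3 was at 0.716 ± 0.225 CPM in PRRX1 doxycycline water and 12.4 ± 0.760 CPM after poly(I:C), with at most 1 count in the 12 libraries of the other groups.

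Doxycycline alone was not without effect: with the Luc insert 393 genes were higher and 314 lower. PCOLCE, an enhancer of procollagen processing, rose by 2.27 ± 0.17, and lower were INHBA, a subunit of activin, at −4.27 ± 0.46, CRH, a stress hormone precursor, at −3.36 ± 0.61 and DBH at −1.70 ± 0.15. The stress list was the only one past the test, with 6 of 23 lower, 14 when adjusted over the list alone, and a median of −0.53 (camera adjusted p = 1.27e-08, and adjusted p = 0.464 with an estimated correlation). TRIB3 fell by 1.36 ± 0.14 there. The count of 707 was 157 without doxycycline replicate 1, 179 without DMSO replicate 2, 1372 with a replicate block, 1095 without the low-count filter and 187 with only these 4 libraries in the fit.

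Taking the Luc effect off the PRRX1 effect left 622 genes higher and 767 lower. CCN2 differed by 9.62 ± 0.70, FN1 by 5.08 ± 0.34, TIMP3 by 4.48 ± 0.21 and WWTR1, the Hippo coactivator TAZ, by 3.52 ± 0.49. MYCN differed by −1.04 ± 0.21 (edgeR adjusted p = 0.0043) and the vesicular transporter SLC18A1 by −2.85 ± 0.27. Mesenchymal markers were higher in 14 and lower in 1 (camera adjusted p = 1.2e-08, and 0.00274 with an estimated correlation), adrenergic markers lower in 17 and higher in 5 (7.82e-08, and 0.00265), matrix genes higher in 15 and lower in 2 (3.09e-13, and 0.00958) and stress genes lower in 14 and higher in 1 (2.66e-12, and 0.0466). CHAC1 differed by −3.30 ± 0.32. Interferon-stimulated genes had 4 higher and 1 lower (adjusted p = 0.0238, and adjusted p = 0.472 with an estimated correlation), and the list did not pass without Luc DMSO replicate 1, Luc doxycycline replicate 1 or PRRX1 doxycycline replicate 2 (adjusted p = 0.117, 0.316 and 0.0656). PRRX1 itself, at 1 to 5 counts in the Luc water libraries, did not pass as a difference (adjusted p = 0.372). The 1389 calls came to 899 and 836 without PRRX1 DMSO replicates 1 and 2, 915 without PRRX1 doxycycline replicate 1 and 894 without Luc doxycycline replicate 2.

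Poly(I:C) was then given to each of these BE2c states. Without PRRX1 induction the cells changed few genes: 12 higher and 9 lower in Luc DMSO, 2 and 4 in Luc doxycycline, 2 and 5 in PRRX1 DMSO, and none of 43 interferon-stimulated genes in any of the 3. As a list these had a median of −0.47 in Luc doxycycline (camera adjusted p = 0.00372, and adjusted p = 0.374 with an estimated correlation), which was 0 without water replicate 2 (adjusted p = 0.927). In PRRX1 DMSO the median was 0.44 (camera adjusted p = 0.0429, and adjusted p = 0.626 with an estimated correlation), and the list did not pass without water replicate 1 or 2 or poly(I:C) replicate 1 (adjusted p = 0.134, 0.132 and 0.247). NPM1, a nucleolar chaperone, fell in each, at −0.70 ± 0.11, −0.66 ± 0.11 and −0.73 ± 0.11. HSPA8, a constitutive heat shock protein, fell in Luc DMSO at −0.80 ± 0.14 and in Luc doxycycline at −1.07 ± 0.14, where TRIB3 rose by 0.91 ± 0.14. In Luc DMSO the vesicular acetylcholine transporter SLC18A3 rose by 1.23 ± 0.19. With only the libraries compared, NPM1 did not pass in any of the 3 (adjusted p = 0.308, 0.177 and 0.0859), nor did HSPA8 and SLC18A3 in Luc DMSO (adjusted p = 0.285 and 0.154). These 3 counts are loose, for without the low-count filter they were 181, 176 and 71, with a replicate block 118, 78 and 38 and by DESeq2 66, 33 and 16. With only the libraries compared they were 2 in Luc DMSO and 3 in PRRX1 DMSO. Luc DMSO came to 12 and 0 without water replicates 1 and 2 and to 11 and 0 without poly(I:C) replicates 1 and 2, Luc doxycycline to 2 without water replicate 1 and 0 without either poly(I:C) replicate, and PRRX1 DMSO to 0 without any 1 of its libraries. In a simulation of the Luc DMSO comparison 56.7% of genes changed 2-fold were found. Simulated genes were set at their mean level over all BE2c libraries, so the share does not hold for genes near 0 without induced PRRX1.

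With PRRX1 induced, 648 genes rose and 492 fell. All 43 interferon-stimulated genes were higher, by a median of 6.33 (camera adjusted p = 3.88e-115, and 0.000234 with an estimated correlation): IFIT1 went from 5.32 ± 1.76 to 808 ± 101 CPM, ISG15 rose by 8.22 ± 0.52, and IFI44L, MX2 and IFIH1, all at 0 in water, rose at least 1020-fold, 764-fold and 420-fold. TLR3 rose from 3 and 4 counts to 62 and 63, by 4.08 ± 0.69 (edgeR adjusted p = 0.0018). CXCL10 rose 1330-fold with a counting interval of 368 to 11000, 1 of 9 cytokine genes that rose of 11. Class I genes rose in 16 and fell in 1 of 19, by a median of 2.55, with PSMB9, an immunoproteasome subunit, at 7.33 ± 0.33 and TAP1, the peptide transporter, at 5.98 ± 0.32. NF-kappaB targets rose in 9 of 22 by a median of 0.83, with ICAM1 at 6.03 ± 0.72 and IRF1 at 3.50 ± 0.24.

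Stress genes, which PRRX1 had lowered, rose in 15 of 23 with poly(I:C), by a median of 1.00, or 0.90 with 0-count genes at their bound (camera adjusted p = 1.1e-12, and 0.0396 with an estimated correlation), CHAC1 by 4.16 ± 0.25 and SESN2 by 2.63 ± 0.20. Cell death genes rose in 12 of 21, with PMAIP1, a BH3-only protein, at 2.24 ± 0.16 and APOL6, also induced by interferon, at 5.61 ± 0.23. CCN2 and FN1 fell, at −1.16 ± 0.18 and −1.09 ± 0.21. Mesenchymal markers moved both ways, 7 higher and 3 lower (adjusted p = 0.0481, and adjusted p = 0.132 with an estimated correlation), and did not pass without water replicate 1 or 2 or poly(I:C) replicate 2 (adjusted p = 0.0649, 0.0617 and 0.129). MYCN did not change by the test, at −0.27 ± 0.15 (adjusted p = 0.348). The count of 1140 was 618 without water replicate 2, 664 without poly(I:C) replicate 1 and 600 without poly(I:C) replicate 2.

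The test of the difference between PRRX1 cells with and without doxycycline called 249 genes higher and 117 lower. Interferon-stimulated genes differed in 32 of 43, 39 when adjusted over the list alone, with a median of 5.67 (camera adjusted p = 2.06e-50, and 0.00144 with an estimated correlation). HLA-C differed by 3.42 ± 0.21, EIF2AK2 by 3.20 ± 0.20 and CHAC1 by 4.49 ± 0.32. The proliferation gene PLK1 differed by −0.95 ± 0.23 and ODC1, the first enzyme of polyamine synthesis, by −0.90 ± 0.22. The 366 calls came to 199 and 218 without DMSO water replicates 1 and 2, 231 without DMSO poly(I:C) replicate 2 and 230 without doxycycline poly(I:C) replicate 2, but to 623 with a replicate block and 574 without the low-count filter. With the same contrast in Luc cells taken off, 87 genes were higher and 14 lower (101 calls, 180 with a replicate block and 232 without the low-count filter), including HLA-C at 3.83 ± 0.32, CHAC1 at 3.91 ± 0.43 and DDIT3 at 2.10 ± 0.38. The interferon list had 19 of 43 higher, 35 when adjusted over the list alone (adjusted p = 1.39e-48, and 0.00289 with an estimated correlation). IFIT1 and ISG15, with few counts in the groups without induced PRRX1, did not pass that last test (adjusted p = 0.277 and 0.106).

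The SH-EP MYCNER clones were examined for what the guide pairs changed, with the clone as the replicate, 2 against 2; the labels state no treatment for these libraries. TLR3 transcript was at 6.43 ± 0.412 CPM with the luciferase and Rosa26 guides, 5.29 ± 2.40 with TLR3/Rosa and 3.24 ± 2.53 with TLR3/MYD88, and did not pass in any comparison (edgeR adjusted p = 0.925, 0.409 and 0.521). A guide cut need not remove the 3' end that is counted, so the TLR3 count checks nothing about the protein. MYD88 fell with the TLR3/MYD88 pair, from 2.90 ± 0.0947 in the control clones and 2.93 ± 0.177 in TLR3/Rosa to 0.319 ± 0.0526 CPM (adjusted p = 0.0202 and 0.00799). With TLR3/MYD88 clone 1 or 2 left out, 1 clone stayed in that group and neither comparison passed, but the log2 fold changes held. They were −3.35 and −3.02 against control and −3.37 and −3.03 against TLR3/Rosa. Without TLR3/Rosa clone 1 the second comparison did not pass either, at −3.12.

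**Figure D4:**
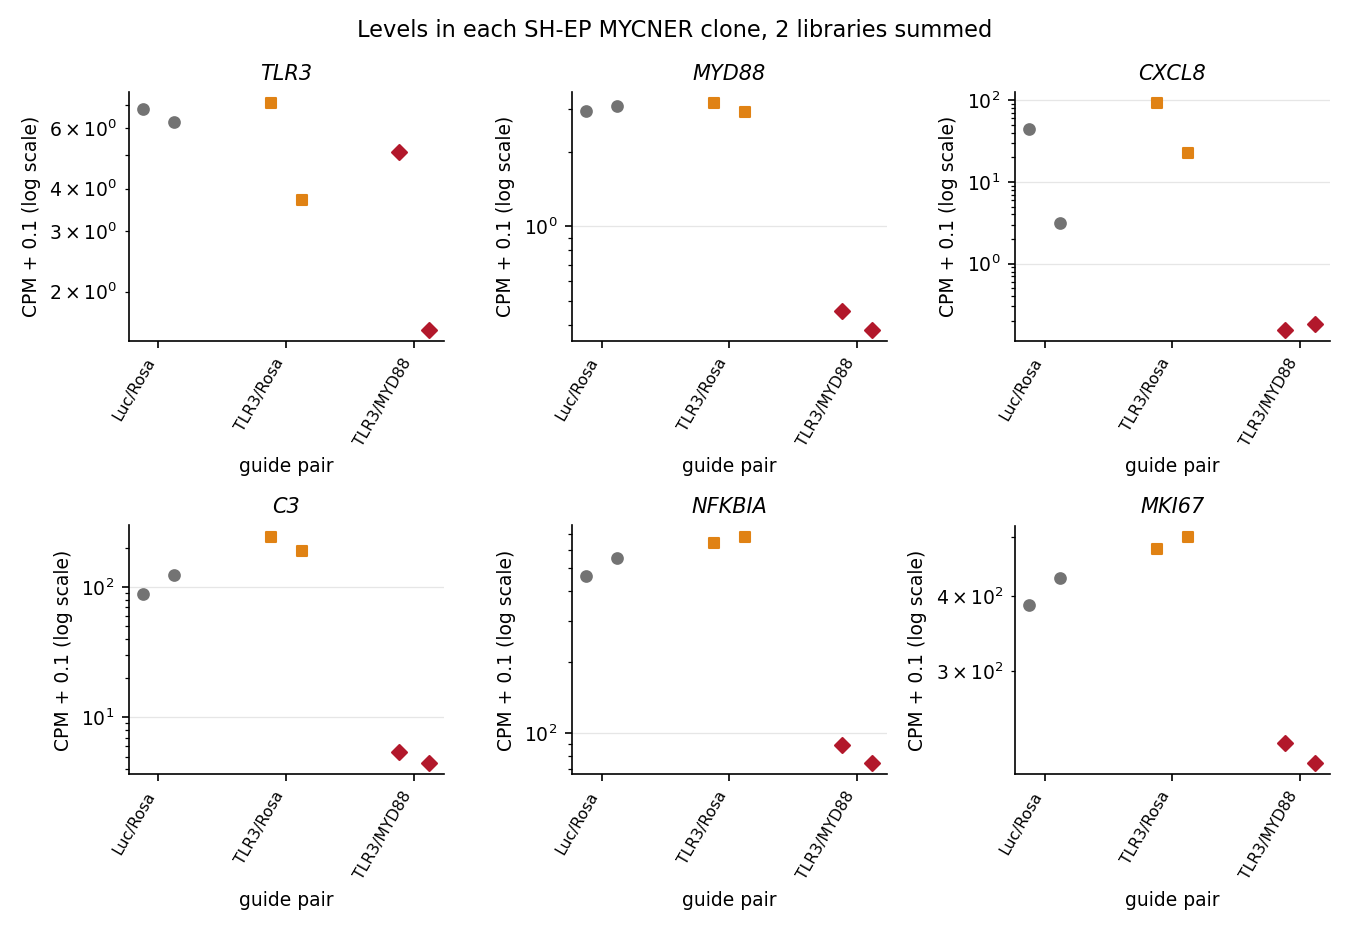
Level of 6 genes in each of 6 SH-EP MYCNER clones, 2 per guide pair and 2 libraries summed per clone, as CPM + 0.1 on a log scale. MYD88 was at 2.90 ± 0.0947 CPM in Luc/Rosa, 2.93 ± 0.177 in TLR3/Rosa and 0.319 ± 0.0526 in TLR3/MYD88 clones (mean ± SD).

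Between TLR3/MYD88 and TLR3/Rosa clones, inflammatory genes were lower with the MYD88 guide. The neutrophil chemoattractant CXCL8 stood at −9.66 ± 1.88, CXCL1 at −9.11 ± 0.79, CXCL2 at −7.67 ± 1.21 and IL6 at −9.27 ± 1.19, and TNF, at 0 in the TLR3/MYD88 clones, fell at least 214-fold. Of 25 cytokine genes 12 fell, 17 when adjusted over the list alone, with a median of −4.02, or −3.52 with 0-count genes at their bound (camera adjusted p = 1.43e-10, and adjusted p = 0.198 with an estimated correlation). NF-kappaB targets fell in 18 of 26, 22 when adjusted over the list alone, by a median of −1.89 (adjusted p = 5.71e-18, and adjusted p = 0.106 with an estimated correlation), with complement C3 at −5.48 ± 0.26, the inhibitor NFKBIA at −3.02 ± 0.15 and RELB at −2.80 ± 0.13. Cell cycle genes fell in 33 of 35, by a median of −1.01 (adjusted p = 1.68e-28, and adjusted p = 0.106 with an estimated correlation), among them AURKB at −1.48 ± 0.12, MKI67 at −1.16 ± 0.10 and E2F1 at −1.22 ± 0.11. Interferon-stimulated genes did not move as a list (adjusted p = 0.6), with OAS3 lower at −1.33 ± 0.12 and IFITM3 higher by 1.54 ± 0.11. Higher genes were IGFBP5, an insulin-like growth factor binding protein, by 8.54 ± 1.23, the granule protein SCG2 by 4.62 ± 0.79 and PTGES, a prostaglandin synthase, by 5.45 ± 1.02. Schwann cell and precursor markers as a list had 1 higher, 3 when adjusted over the list alone (adjusted p = 0.0106, and adjusted p = 0.274 with an estimated correlation, and 0.0549 without the low-count filter). The test called 284 genes higher and 642 lower, and the 926 calls came to 11 and 15 without TLR3/MYD88 clones 1 and 2 and 66 and 139 without TLR3/Rosa clones 1 and 2, but to 2402 by DESeq2, 2145 without the low-count filter, 4173 with each library as a replicate and 3825 with a replicate block added to that.

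Against the luciferase and Rosa26 clones, the TLR3/MYD88 clones had 27 genes higher and 198 lower. Lower were C3 at −4.45 ± 0.25, NFKBIZ at −4.23 ± 0.27, BIRC3 at −4.12 ± 0.26 and CXCL1 at −6.93 ± 0.74, and 25 of 35 cell cycle genes fell by a median of −0.87 over the list (camera adjusted p = 4.49e-28, and adjusted p = 0.11 with an estimated correlation). RGS4, which dampens G protein signalling, rose by 3.99 ± 0.49 and the neurotrophin BDNF by 2.29 ± 0.21. IGFBP5, SCG2 and PTGES were not among the 6 largest increases against control. IL6, at −6.98 ± 1.18 against control, did not pass (edgeR adjusted p = 0.0567). Its level was 6.42 ± 6.21 CPM in control and 31.4 ± 14.3 CPM in TLR3/Rosa clones. TLR3/Rosa clones differed from the control clones in 1 gene, with 1139 below an unadjusted p of 0.05 and 171 called by DESeq2; NF-kappaB targets were higher there by a median of 0.41 (adjusted p = 3.82e-08, and adjusted p = 0.563 with an estimated correlation). In a simulation of that comparison 41.8% of genes changed 2-fold were found. MYCN did not pass in any comparison of clones, at 0.56 ± 0.70 for TLR3/MYD88 against control (adjusted p = 0.704). With 2 clones per pair the counts were unsteady: the 225 calls came to 0 without either TLR3/MYD88 clone, 2695 without control clone 2, 1490 by DESeq2 and 1485 without the low-count filter, and the 1 call of TLR3/Rosa against control to 2 and 69 without control clones 1 and 2 and 0 and 7 without TLR3/Rosa clones 1 and 2.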

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

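The checks on these values were fixed before the values were seen; the values themselves were found by going through the results. Of 72 groups of 4 values that were looked at, 5 held a value set apart from the other 3 by a gap above the limit of Dixon's test, and chance alone gives about 1 in 20 groups.

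With poly(I:C), the mean log2 fold change of the stress list was 1.24 in SK-N-AS and 0.341 to 0.378 in the other 3 mesenchymal lines. Mean log2 CPM of MYCN in water was 11.1 in CHP-212 and 1.33 to 2.74 in the other mesenchymal lines. TLR3 in water was at a log2 CPM of −1.1 in SK-N-DZ and −1.39 in the other adrenergic lines, which rests on 1 count. PRRX1 was at 0.0399 CPM in replicate 1 of TLR3/Rosa clone 1 and 0.222 to 0.23 CPM in the other 3 libraries of that pair, again 1 count. MYCN was at 226 CPM in replicate 2 of TLR3/MYD88 clone 1 and 323 to 341 CPM in the others of that pair.

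Effects that differed between groups by a test of the difference itself were the poly(I:C) response of mesenchymal and adrenergic lines, with 247 genes, the doxycycline effect with PRRX1 and with Luc, with 1389, the poly(I:C) response of PRRX1 cells with and without doxycycline, with 366, and that difference with PRRX1 and with Luc, with 101. For the panel, 1 of 35 splits of the 8 lines reached 247 genes, the real one, and the highest of the others had 3. No other split came near that count, but 1 of 35 is the smallest share this test can give. It cannot tell state from other traits that divide the lines the same way. BE2c, with 2 libraries per group, allowed no such count of splits.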

How the results depend on the processing

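All settings were fixed before the data were examined, and no tests here were chosen after the result was seen. Leaving out a library leaves 1 library in its group, which is assumed to vary like the other groups. Size factors by RLE moved no count by over 1.5 times. A value was counted as turned over only if its sign changed and it passed in at least 1 of the settings compared. Of the named genes' values, 1 turned over: PRRX1 between state groups in water, at −0.30 with the line as replicate, was 1.88 with each library as a replicate. That setting averages log levels over the lines, while the main fit takes 1 mean per state. The sign change therefore need not come from the choice of replicate.

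The replicate number was checked for pairing: the deviations of same-numbered libraries correlated at 0.043 to 0.188 within panel lines, and at −0.022 to 0.396 between BE2c groups (median 0.214), against −0.211 to 0.267 between panel groups of different lines (median 0.041). Not every pair was above 0.1 and no label ties the numbers together, so the libraries were taken to share only a number, though the positive values leave a common batch possible. With a replicate block the counts were 57 in Kelly, 30 in SK-N-DZ, 1372 for doxycycline in Luc, 118, 78 and 38 for poly(I:C) in Luc DMSO, Luc doxycycline and PRRX1 DMSO, 623 and 180 for the PRRX1 difference and its difference from Luc, and 290, 2960 and 3825 for TLR3/Rosa against control, TLR3/MYD88 against control and TLR3/MYD88 against TLR3/Rosa with 12 libraries; no other count moved by over 1.5 times.

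Without the low-count filter the counts were 117 in Kelly, 51 in NLF, 93 in SK-N-DZ, 62 in IMR5, 633 for the difference in response, 1095 for doxycycline in Luc, 181, 176 and 71 for poly(I:C) in Luc DMSO, Luc doxycycline and PRRX1 DMSO, 574 and 232 for the PRRX1 difference and its difference from Luc, and 184, 1485 and 2145 in the clone comparisons. By DESeq2 they were 31 in Kelly, 28 in SK-N-DZ, 1 in IMR5, 960 in water between states, 1231 for the difference in response, 66, 33 and 16 for poly(I:C) in the 3 BE2c groups without induced PRRX1, and 171, 1490 and 2402 in the clones. With the 4 libraries of a line fitted alone they were 113 in Kelly, 6 in NLF, 2 in SK-N-DZ and 15 in IMR5, and with only the BE2c libraries compared 187 for doxycycline in Luc, 2 for poly(I:C) in Luc DMSO and 3 in PRRX1 DMSO. With each library as a replicate 9736 genes were called in water, 4705 in the difference in response, and 462, 3365 and 4173 in the clones.

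Leaving out a panel library gave 1270 to 1471 in SH-EP (1270 without water replicate 1, 1313 and 1443 without poly(I:C) replicates 1 and 2), 1233 to 1502 in CHP-212 (1353 and 1282 without water replicates 1 and 2, 1233 without poly(I:C) replicate 1), 0 to 14 in Kelly (14 and 0 without water replicates 1 and 2, 0 without poly(I:C) replicate 1), 1 to 2 in NLF (1 without either water replicate or poly(I:C) replicate 1) and 7 to 132 in SK-N-DZ (25 and 7 without water replicates 1 and 2, 132 without poly(I:C) replicate 2). Leaving out a line gave 0 to 188 in water (4 without SH-EP, 53 without SK-N-AS, 0 without GI-M-EN, Kelly or SK-N-DZ, 15 without CHP-212, 188 without NLF, 3 without IMR5) and 49 to 687 in the difference in response (687 without SH-EP, 602 without CHP-212, 49 without Kelly, 56 without NLF, 51 without SK-N-DZ or IMR5).

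In BE2c, leaving out a library gave 157 to 686 for doxycycline in Luc (157 without doxycycline replicate 1, 179 without DMSO replicate 2), 2334 to 2839 in PRRX1 (2460 and 2334 without DMSO replicates 1 and 2) and 836 to 1200 in their difference (899 and 836 without PRRX1 DMSO replicates 1 and 2, 915 without PRRX1 doxycycline replicate 1, 894 without Luc doxycycline replicate 2). For poly(I:C) it gave 0 to 12 in Luc DMSO (12 and 0 without water replicates 1 and 2, 11 and 0 without poly(I:C) replicates 1 and 2), 0 to 4 in Luc doxycycline (2 without water replicate 1, 0 without either poly(I:C) replicate), 0 in PRRX1 DMSO without any 1 of its libraries, 600 to 919 in PRRX1 doxycycline (618 without water replicate 2, 664 and 600 without poly(I:C) replicates 1 and 2) and 199 to 322 in the PRRX1 difference (199 and 218 without DMSO water replicates 1 and 2, 231 without DMSO poly(I:C) replicate 2, 230 without doxycycline poly(I:C) replicate 2). Among the clones it gave 0 to 69 for TLR3/Rosa against control (2 and 69 without control clones 1 and 2, 0 and 7 without TLR3/Rosa clones 1 and 2), 0 to 2695 for TLR3/MYD88 against control (0 without either TLR3/MYD88 clone, 2695 without control clone 2) and 11 to 139 for TLR3/MYD88 against TLR3/Rosa (66 and 139 without TLR3/Rosa clones 1 and 2, 11 and 15 without TLR3/MYD88 clones 1 and 2).

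Of 974 values of named genes, 30 were weaker and 8 stronger by DESeq2, and 10 weaker and 22 stronger without the low-count filter; of 5145 values with a library, line or clone left out, 1005 were weaker, 16 stronger and none turned over.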

Other observations

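The tests on HOXC4, on the level of TLR3 in water and on the level of MYCN in the clones were chosen after the result was seen. Those on depth, on the spread between replicates and on pairs of clones were recorded as fixed before their result. They address patterns already seen in the calls, however. The splits of the lines were fixed before.

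Beyond the lists named in the report, SK-N-AS raised 3 further genes from 0 counts with poly(I:C), at least 1100-fold for SERPINB2, a plasminogen activator inhibitor, 713-fold for the collagenase MMP13 and 532-fold for the matrix protein SPARCL1 (n = 2 against 2). NT5E, an ectoenzyme that makes adenosine, rose in each mesenchymal line, by 1.45 ± 0.17 in SH-EP, 3.11 ± 0.19 in SK-N-AS, 2.01 ± 0.18 in GI-M-EN and 2.32 ± 0.18 in CHP-212. LUM, a collagen-binding proteoglycan, rose by 2.67 ± 0.18 in GI-M-EN and by 1.52 ± 0.29 in BE2c with induced PRRX1. Hypoxia and glycolysis genes rose in 11 and fell in 3 of 21 in GI-M-EN (adjusted p = 0.0112, and adjusted p = 0.0572 with an estimated correlation).

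Further genes differed between doxycycline and DMSO in BE2c PRRX1 cells in water, with the Luc effect not taken off. KRT18, a keratin of simple epithelia, rose by 4.12 ± 0.34. CCL2, an attractant of monocytes, rose 121-fold with a counting interval of 41.1 to 588. NEDD9, a scaffold of focal adhesions, rose 217-fold with an interval of 38.7 to 8620. VEGFA stood at −2.55 ± 0.20 (−1.11 ± 0.18 with Luc) and the BH3-only genes PMAIP1 at −2.28 ± 0.16 and BBC3 at −2.00 ± 0.21. In TLR3/MYD88 clones against control, the Hedgehog coreceptor BOC was at 3.61 ± 0.54, the ephrin EFNB3 at 3.23 ± 0.30 and DLX2, a homeobox factor of the forebrain and neural crest, at 2.50 ± 0.22, while PTX3, a soluble pattern recognition protein, was at −5.41 ± 0.53 (2 clones against 2).

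More genes passed the test in SK-N-AS and GI-M-EN than in SH-EP and CHP-212 after poly(I:C). Depth did not account for it, since with every panel library thinned to 3.44 M counts the smaller of the first pair still had 2.91 times the count of the larger of the second, against 2.77 before. A tighter spread between replicates was also considered. The 16 panel groups shared the same estimate of the spread, so tighter replicates would not lower it for SK-N-AS and GI-M-EN alone. Chi-square per degree of freedom of the water and poly(I:C) pairs was 4.95 and 4.158 in SK-N-AS and 6.093 and 4.922 in GI-M-EN. It was 4.586 and 4.776 in SH-EP and 3.533 and 4.395 in CHP-212. Neither SK-N-AS nor GI-M-EN was tighter in both pairs, which argues against this explanation. The interquartile range of fold changes does not measure the replicate spread. That range was at least 1.92 times as wide in SK-N-AS and GI-M-EN as in SH-EP and CHP-212. Basal TLR3 was tested too. Its lowest mean was in GI-M-EN, and that of SH-EP was 2.43 times as high. Both water libraries of GI-M-EN, at 0.405 and 2.49 CPM, lay below those of SH-EP and CHP-212, but hold only 2 and 14 counts of it. The gap between the means of GI-M-EN and SH-EP, 1.45 and 3.52 CPM, was smaller than the SD in CHP-212, 2.54 CPM. By its rule the test therefore did not decide. The response was broader in SK-N-AS and GI-M-EN, with 3791 and 3214 called genes of at least 2-fold against 762 in SH-EP and 860 in CHP-212. It was not stronger for every list. The interferon list averaged 5.613 in SK-N-AS, 6.972 in GI-M-EN, 3.484 in SH-EP and 6.308 in CHP-212. The NF-kappaB list averaged 4.914 in SK-N-AS and 4.442 in GI-M-EN, against 1.056 in SH-EP and 2.075 in CHP-212. Cytokine and cell death lists separated the lines the same way. Mesenchymal markers, at 0.229 in GI-M-EN and 0.237 in SH-EP, did not. The basis of the broader response remains open.

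HOXC4 and ENSG00000273266 changed places between BE2c libraries, and both were called with poly(I:C) in Luc DMSO. The SD of their summed counts over 16 libraries was 0.0657 of the smaller SD of either gene alone, while HOXC4 differed between replicates of one group by 1.02 times the range of the group means. Reads of one locus assigned to one gene or the other may account for the calls, which argues against a response of HOXC4 in BE2c. In Kelly HOXC4 was at 0 in both water libraries and at 54.8 and 61.8 CPM after poly(I:C) while ENSG00000273266 was at 69.13 and 70.64 and then at 1.711 and 1.16 CPM. The 2 thus moved in opposite directions by amounts of similar size there too. Reads assigned to one gene or the other may account for it, which was not tested in Kelly, so no response of HOXC4 is shown. Over 30 replicate pairs, 21 genes were at 0 in one library and at 20 CPM or more in the other, ENSG00000229874 in 9 pairs and MSANTD3-TMEFF1 in 7, so single calls on such genes carry little weight.

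In the TLR3/MYD88 clones NF-kappaB, cytokine and cell cycle genes were lower together. Their MYCN level did not set them apart, because both of the 2 clones, at 266 and 323 CPM, lay within the 59.5 to 340 CPM of the 4 other clones while their NF-kappaB scores, −1.23 and −1.37, lay below all 4. Of the 15 pairs that 6 clones allow, 1 differed as much in that score, the real one at −1.95, with 1.31 the highest of the others, and 15 pairs are too few for a share below 0.05. Differences between clones unrelated to the guides therefore cannot be told apart from an effect of MYD88 loss, which may be tested with more clones.

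Between state groups in water, 1 of 35 splits of the 8 lines into 4 and 4 reached 34 calls, the real one. The highest of the others called 2. No other split came near, but 1 of 35 is the smallest share this test can give. It cannot tell state from other traits that divide the lines the same way. The count of 34 was 0 without GI-M-EN, Kelly or SK-N-DZ, 4 without SH-EP and 53 without SK-N-AS. It was 15 without CHP-212, 188 without NLF and 3 without IMR5.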
